A study of Mus musculus with 24 samples.

How the data were processed

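RNA was profiled on 24 one-colour Affymetrix arrays, 3 in each of 8 groups. Per the labels, the cells were embryonic cortical neurons from Il1rap-/- mice, which lack the IL-1 receptor accessory protein AcP, made to express CD25, AcP, AcPb or both AcP and AcPb. Each of the 4 receptor arms received IL-1b at 10 ng/ml or a control stimulus for 4 h. RNA was taken with a column kit and labelled with biotin by the Eberwine method, per the labels' protocols. The groups were taken from the labels, and every array had a group.

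The deposited values are linear probe set intensity values. How probe sets were summarised and scaled is not given in the sources used here. The values ran from -1617.3 to 13068.67, with array medians between 55 and 66.4. Between 16.4% and 18.22% of the values of an array lay below 0, as a subtracted background leaves them. No detection calls were used here, so a dim gene cannot be told from an absent one, and the number of arrays limits the precision. No array pair held identical values.

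Of 45077 probe sets, 40 control probe sets were left out. The probe set to gene table supplied with the series paired 34945 of the other 45037 with 1 gene symbol and 932 with several, and 9160 had none. Symbols were checked against RefSeq names of assembly GRCm38.p6 through Entrez IDs, which matched 34741 probe sets and changed 0 symbols. For each of 18193 genes the probe set with the highest mean was used. A gene was tested if at least 3 arrays lay above the 40th percentile of their array, which left 14221 genes. Of 43 pairs of a named gene and a comparison where the gene had several probe sets, 27 had a further probe set that was uncalled or opposite in sign. The probe set with the highest mean need not be the most responsive, so a change can be larger on another.

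The plan was to test log2(value + 16) if the values were linear. Because many values lay below 0, negative values were set to 0 before adding 16, a step that the plan did not hold, and a generalised log that keeps negative values was added as an alternative after seeing the data. Fold changes are on the log2(value + 16) scale, which understates the change of dim genes and, where a group lies near or below 0, depends on the added 16. Mean intensities are therefore given beside many of them, and a fold change given without them can rest on the added 16.

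The model was fitted with limma (version 3.58.1, R 4.3.3) through lmFit and eBayes on all 24 arrays with 8 group means, which gave 16 residual and 1.95 prior degrees of freedom. The 11 comparisons were the IL-1b response in each arm, 4 differences between the responses of a pair of arms, and 3 comparisons between unstimulated arms. P-values were adjusted by Benjamini-Hochberg within each comparison, are two-sided, and a gene was called at an adjusted p under 0.05. The values after ± are standard errors of limma's log2 changes, or SDs of 3 arrays where an intensity is given. With 3 arrays against 3, an exact permutation test of a single gene cannot give a two-sided p under 0.1, and none was used. Nothing in the labels says that the 3 arrays of a group came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

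The 20 gene lists covered chemokines, cytokines and growth factors, the NF-kB pathway and its feedback, the IL-1 receptor family and proximal signalling, acute phase and complement genes, adhesion and proteolysis, prostaglandin and nitric oxide synthesis, the interferon response, and immediate early genes. They also covered neuron markers, synaptic receptors and channels, neuropeptides, 5 lists of other cell types, apoptosis, stress and reference genes. They held 489 members, of which 447 were named on the array and 369 tested. A member dim without IL-1b passes the dim filter more readily if it rises, and no list was tested without the filter. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 20 lists of a comparison, and again with an estimated correlation and with fry, whose directional test is meant unless its mixed test is named. Calls of list members were also adjusted over the list alone.

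The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named up to 12 rises and 8 falls of each response or difference, by size, among called genes whose arrays did not overlap between groups. For unstimulated comparisons it named 6 rises and 6 falls, from each list up to 4 members with the largest change, and always Il1rap, Il2ra, Il1r1, Il1r2 and Il1rn. For a difference between responses the adjusted p alone was required. Some genes that the rule named in a comparison are also given in others where it did not name them, such as the CD25 and AcPb responses. Gene families chosen later are said to be so.

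Alternatives changed 1 choice at a time. They were quantile normalization, centring of array medians, no dim filter or one at the 60th percentile, the mean of a gene's probe sets, all probe sets tested singly, only the arrays compared, an intensity trend, array weights, the replicate number as a block, a code in the array names as a block, pseudocounts of 1 and 64, and leaving out each array in turn. The array names carry 3 codes of unstated meaning. All 18 arrays of the CD25, AcP and AcPb arms share a code, whereas AcP+AcPb controls 1 and 2 have another and AcP+AcPb control 3 and the 3 AcP+AcPb IL-1b arrays have yet another.

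The fits were tested on simulated data with the real genes. In the simulated AcP response, 58% of genes changed by 0.5 log2 units were called, 84% of those changed by 1, 98% of those changed by 2 and 100% of those changed by 4, with 6 calls among unchanged genes. In the simulated difference between AcP and CD25 responses the shares were 44%, 70%, 94% and 100%, with 8 such calls. The simulated CD25 response, made with no change, gave 0 calls. The list test called the 1 shifted list and 0 of the 19 others. The simulated genes varied independently, so this does not check the list test where the genes of a list are correlated. Each gene had the same simulated SD in every group, so unequal spread between groups was not simulated. Rises and falls were added on the log2 scale without the floor that setting negative values to 0 gives. Dim genes could thus fall further than real values can, and the shares called may be too high.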

Results

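The study asked whether AcP, the accessory chain of the IL-1 receptor, or AcPb, an isoform of AcP made in the nervous system from the same gene, lets neurons without either chain respond to IL-1b, and what AcPb does when AcP is also present. CD25, the alpha chain of the IL-2 receptor, is not part of the IL-1 receptor, and its arm is the comparison without an accessory chain. Each of the 4 arms had 3 control and 3 IL-1b arrays, taken at 4 h. Array medians ran from 55 to 66.4 intensity units, and replicate arrays correlated at a mean of 0.976 to 0.9865 within groups. The AcP controls were the widest group, with a median SD of 0.165 log2 units against 0.089 to 0.116 in the others. Il1rap, the gene of both AcP and AcPb, lay between 111 and 136 in every group on its brightest probe set. Il2ra, the gene of CD25, lay between 19.2 and 37.7, with 37.7 ± 2.03 in CD25 controls. Introduced coding sequences need not hold the stretch that an array probes, so these levels check no label. Il1rn, the gene of the IL-1 receptor antagonist, lay between 54.0 and 95.7. Both probe sets of Il1r1, the signalling IL-1 receptor, had means below 0 in every group, and the gene was not tested. Il1r2, the decoy receptor, lay between -2 and 52, and none of these genes was called in any IL-1b response.

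In neurons with AcP, IL-1b raised members of the chemokine and NF-kB lists, by up to 90.5-fold on the probe set used for each gene. Bulk arrays do not show which cells responded. Astrocyte markers averaged 10.39 log2 units in AcP controls, beside 11.31 for neuron markers. Cxcl10, a chemokine that attracts activated T cells, rose by 6.50 ± 0.32 log2 units, from 13.5 ± 15.8 to 2512 ± 277 intensity units (n = 3 each, adjusted p = 4.5e-10). Ccl2, which attracts monocytes, rose by 3.41 ± 0.21, from 60.3 to 798, and Cxcl2, which attracts neutrophils, by 2.85 ± 0.24. Tnfaip2 rose by 4.82 ± 0.23 (adjusted p = 4.5e-10) and Nfkbiz, a nuclear regulator of NF-kB target genes, by 2.98 ± 0.18, from 56.3 to 556. Lcn2, an iron-scavenging defence protein, rose by 3.48 ± 0.32, the pentraxin Ptx3 by 3.40 ± 0.27 and the metalloreductase Steap4 by 3.85 ± 0.31 from a control mean below 0. Gbp2, an interferon-inducible GTPase, rose by 4.26 ± 0.27, from -1.85 to 347, and the leukocyte adhesion molecule Icam1 by 3.27 ± 0.30, from 12.5 to 274. The transcription factor Cebpd rose by 3.26 ± 0.26, and Trim47 rose by 2.74 ± 0.51, from -67.3 to 93.1. Falls were smaller. The Notch receptor gene Notch2 fell by 0.67 ± 0.12, from 522 to 322, with its other probe set uncalled at -0.43 (adjusted p = 0.59). Nrarp, a feedback regulator of Notch signalling, fell by 0.54 ± 0.09, from 669 to 455, with its other probe set uncalled at -0.33 (adjusted p = 0.23). Mertk, a receptor for the clearance of dying cells, fell by 0.57 ± 0.10, Fyco1 fell by 0.60 ± 0.08, Cspp1 fell by 0.67 ± 0.14, A930013F10Rik fell by 0.66 ± 0.13, and the dim genes Six3os1 and Sprr2k fell by 0.79 ± 0.15 and 1.55 ± 0.34.

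By limma, 76 of 14221 genes were called in AcP neurons, 63 higher and 13 lower, of which 39 changed at least 2-fold. At an unadjusted p under 0.05 there were 1249 genes, against 711 from chance. In all 76 the IL-1b arrays lay apart from the controls, as in 10.6% of all genes, where chance gives 10%. Ccl2, Cebpd, Cxcl10, Cxcl2, Gbp2, Nfkbiz, Ptx3, Steap4 and Tnfaip2 were called under every alternative. Tested singly, a further probe set each of Cebpd, Steap4 and Tnfaip2 was not called (adjusted p = 0.35, 0.063 and 0.96). Sprr2k lost its call in 14 of 19, Cspp1 in 10 of 20 and A930013F10Rik in 7 of 19. Trim47, Notch2 and Mertk lost theirs in 5 of 20 each and Six3os1 in 5 of 19. The count was 189 without AcP control 3, 50 without AcP control 2, 38 without AcP IL-1b array 2, 34 with array weights, 31 with only these 6 arrays in the fit and 123 over single probe sets.

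Of the 20 gene lists, 6 rose in AcP neurons under both the preset and the estimated correlation. The members counted are those past the dim filter, which favours dim genes that rise. Of 16 chemokines, 6 rose and 0 fell, also when adjusted over the list alone, with Cxcl10, Ccl2, Cxcl2 and Cxcl1, which rose by 2.25 ± 0.19, in front (camera adjusted p = 3.6e-11, and 0.00029 with an estimated correlation). Tested singly, the dimmer Cxcl1 probe sets rose by more, 7.05 ± 0.29 and 4.35 ± 0.24. Among 20 NF-kB genes 5 rose, and 13 when adjusted over the list alone, including Nfkbie by 1.21 ± 0.20 and Nfkbia, the inhibitor that NF-kB induces against itself, by 0.97 ± 0.08 (3.6e-19, and 2e-06 as adjusted p with an estimated correlation). Of 17 acute phase and innate defence genes 4 rose, Steap4, Lcn2, Ptx3 and the receptor gene Tlr2 by 1.93 ± 0.16, and 7 when adjusted over the list alone (7.9e-11, and 0.00071 as adjusted p with an estimated correlation). Of 23 interferon response genes 5 rose, and 7 when adjusted over the list alone, among them Gbp2, Gbp3 by 1.75 ± 0.25, Irf1 by 1.66 ± 0.31 and Irgm1 by 1.30 ± 0.12 (1e-06, and 0.0011 as adjusted p with an estimated correlation). Of 36 immediate early and MAPK feedback genes 8 rose, and 13 when adjusted over the list alone, with Cebpd, Atf3 by 2.29 ± 0.30, Ier3 by 2.26 ± 0.18 and Egr2 by 2.21 ± 0.20 (4.7e-18, and 0.0011 as adjusted p with an estimated correlation). Of 17 adhesion and proteolysis genes 3 rose, with Icam1 and the protease gene Adamts1 at 1.40 ± 0.16 in front, and 5 rose and 1 fell when adjusted over the list alone (0.0033, and 0.039 as adjusted p with an estimated correlation).

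A further 3 lists moved at the preset but not the estimated correlation, without a member called over all genes. Adjusted over the list alone, 1 progenitor marker fell and 2 apoptosis genes rose. The lists were oligodendrocyte markers, lower (adjusted p = 0.018, and 0.39 with an estimated correlation), progenitor and dividing cell markers, lower (adjusted p = 0.0047, and 0.31 with an estimated correlation), and apoptosis genes, higher (adjusted p = 0.0047, and 0.063 with an estimated correlation), of which only the apoptosis genes also passed fry (adjusted p = 0.02). Neither neuron markers, with changes between -0.06 and 0.16, nor astrocyte or microglia markers passed the test. The other lists were cytokines and growth factors, IL-1 receptor family genes, prostaglandin and nitric oxide synthesis, synaptic receptors and channels, neuropeptides, endothelial, mural and fibroblast markers, stress genes and reference genes. Their adjusted p-values and those of the neuron, astrocyte and microglia lists ran from 0.068 to 0.97. Reference genes changed by -0.17 to 0.16.

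**Figure D1:**
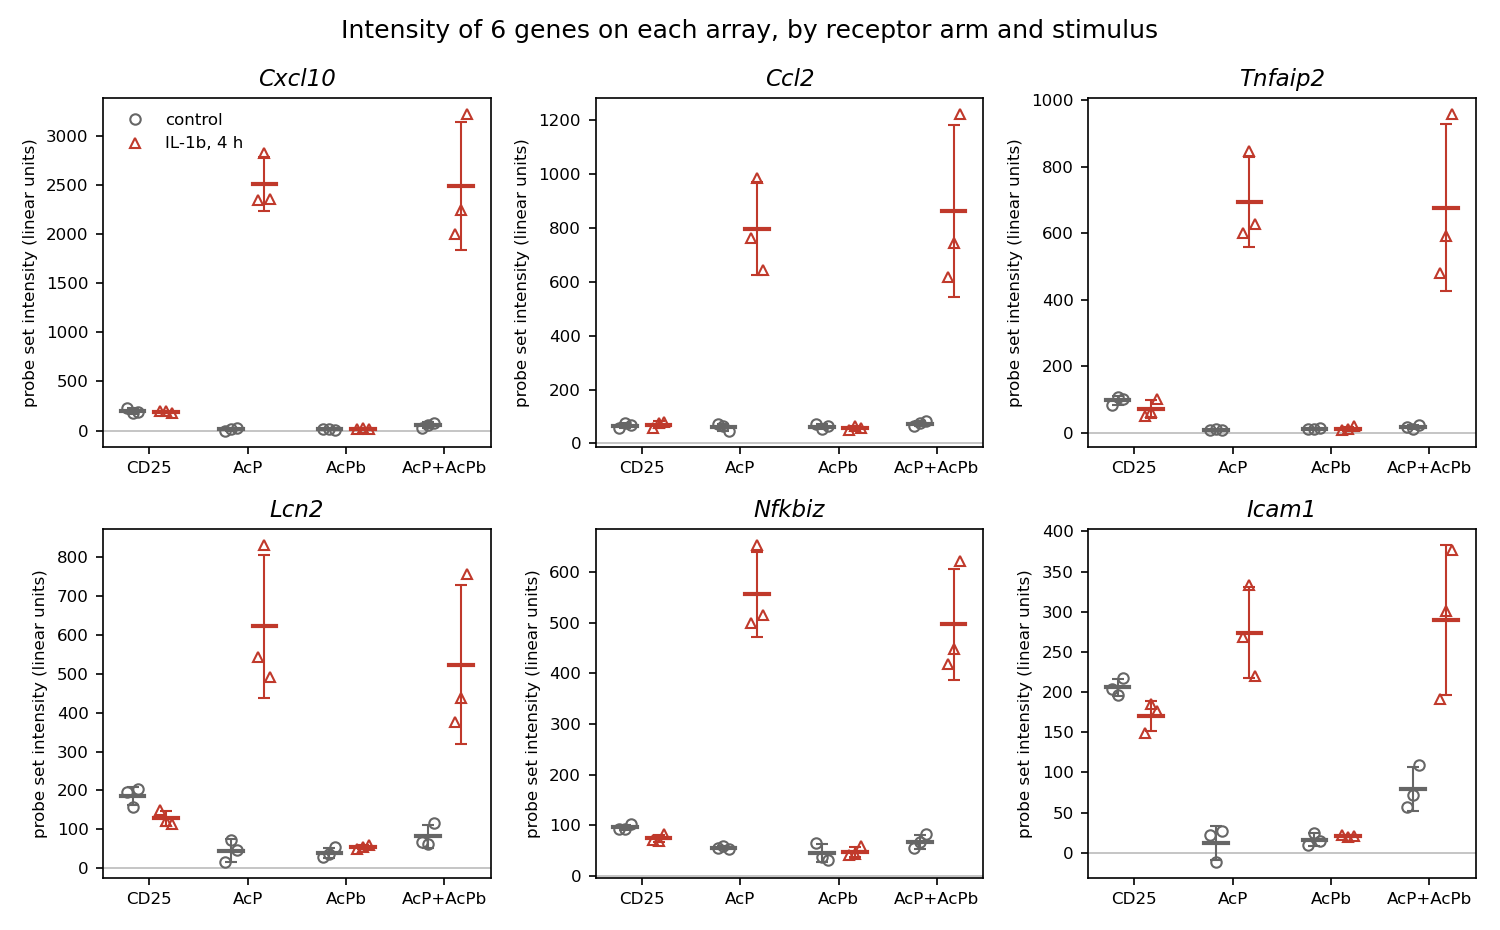
Probe set intensity (linear units) of Cxcl10, Ccl2, Tnfaip2, Lcn2, Nfkbiz and Icam1 on each of the 24 arrays, by receptor arm, with control arrays as grey circles, IL-1b arrays as red triangles, and the mean and SD of 3 arrays as bars. Cxcl10 means were 2512 and 2489 after IL-1b in the AcP and AcP+AcPb arms and 20.0 in the AcPb arm.

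In neurons with CD25, the genes that rose with AcP gave no call after IL-1b. The log2 change was -0.04 ± 0.32 for Cxcl10, 0.06 ± 0.21 for Ccl2, -0.31 ± 0.18 for Nfkbiz and 0.08 ± 0.08 for Nfkbia. Chemokines changed by -0.44 to 0.57, NF-kB genes by -0.41 to 0.39, and 0 of the 20 lists was called at either correlation or with fry. limma called 0 of 14221 genes, with 864 at an unadjusted p under 0.05 against 711 from chance, and 13.7% of genes without overlap where chance gives 10%. Array weights gave 2 calls, and leaving out CD25 control 2 or CD25 IL-1b array 3 gave 1 each.

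In neurons with AcPb alone, the same inflammatory genes gave no call. Cxcl10 had 12.5 ± 6.74 in controls and 20.0 ± 1.49 after IL-1b, Ccl2 had 62.3 ± 10.1 and 56.9 ± 8.28, Tnfaip2 had 13.4 ± 2.04 and 13.0 ± 6.42, and Cebpd had 76.9 ± 4.30 and 77.0 ± 10.1. Chemokines averaged 6.56 log2 units in AcPb controls and 6.76 after IL-1b, with SDs of 0.04 and 0.10. NF-kB genes averaged 7.11 and 7.12, and acute phase genes 6.32 and 6.36. Of the 20 lists 0 was called at either correlation or with fry's directional test, and 1 with the replicate number as a block. Fry's mixed test, which asks for changes in any direction, called synaptic receptors and channels (adjusted p = 0.0021) and the IL-1 receptor family (adjusted p = 0.019). Adjusted over the list alone, 1 of 33 synaptic receptor and channel genes rose and 4 fell, 1 of 36 immediate early genes rose and 1 fell, and 1 of 17 adhesion genes rose. The only called gene was Peak1, a pseudokinase gene, which fell by 1.19 ± 0.14, from 173 ± 11.4 to 68.6 ± 19.6 (adjusted p = 0.0024), and it lost its call in 2 of 20 alternatives. The 3 further Peak1 probe sets were not called.

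At an unadjusted p under 0.05 the AcPb response held 1555 genes, against 711 from chance, and 23.1% of genes did not overlap, against 10%. The count of calls was 179 with array weights, 74 higher and 105 lower, 3 over single probe sets, 2 without the dim filter, at the 60th percentile or with an intensity trend, and 0 with the mean of probe sets or with only these 6 arrays. It was 3 without AcPb control 1, 2 without AcPb IL-1b array 1 and 4 without AcPb IL-1b array 3.

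In neurons with both AcP and AcPb, IL-1b again raised Cxcl10, Ccl2, Tnfaip2 and other genes that it raised with AcP alone. Cxcl10 rose by 5.22 ± 0.32 log2 units, from 54.3 ± 29.1 to 2489 ± 649 (adjusted p = 1.5e-08), Ccl2 by 3.24 ± 0.21, Cxcl2 by 2.55 ± 0.24 and Cxcl1 by 1.97 ± 0.19, with 6.19 ± 0.29 and 3.90 ± 0.24 on its dimmer probe sets. Tnfaip2 rose by 4.30 ± 0.23, Gbp2 by 4.05 ± 0.27, Steap4 by 4.00 ± 0.31, Ptx3 by 3.44 ± 0.27 and Nfkbiz by 2.60 ± 0.18. Lcn2 rose by 2.44 ± 0.32, from 81.8 to 524, Egr2 by 2.06 ± 0.20 and Cebpd by 2.00 ± 0.26, from 157 to 653. The lipid transporter gene Abca2 fell by 1.95 ± 0.32, from 115 to 21, Tex26 fell by 1.54 ± 0.31, Plin2, which coats lipid droplets, fell by 0.59 ± 0.10, and Nrarp fell by 0.55 ± 0.09, from 659 to 447, with its other probe set uncalled at -0.34 (adjusted p = 0.22). Filip1 fell by 0.53 ± 0.10, Vstm4 fell by 0.48 ± 0.09, Usp4 fell by 0.45 ± 0.08 and D130043K22Rik fell by 0.43 ± 0.09.

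By limma, 65 genes were called in AcP+AcPb neurons, 47 higher and 18 lower, 28 of them at least 2-fold, with 1580 at an unadjusted p under 0.05 and 18.1% of genes without overlap, where chance gives 10%. Ccl2, Cxcl10, Gbp2, Nfkbiz, Steap4 and Tnfaip2 were called under every alternative. Tested singly, a further probe set each of Nfkbiz and Tnfaip2 was not called (adjusted p = 0.13 and 0.95). D130043K22Rik lost its call in 13 of 20, Vstm4 in 9 of 19, Usp4 in 8 of 20, Tex26 in 6 of 19 and Filip1 in 4 of 20. The count was 34 without AcP+AcPb control 2, 120 without AcP+AcPb control 3, 29 without AcP+AcPb IL-1b array 3, 42 with array medians centred, 23 with the array code as a block and 9 with only these 6 arrays.

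Lists called at both correlations in AcP+AcPb neurons were chemokines (5 of 16 rose, and 6 adjusted over the list alone, camera adjusted p = 3.7e-10), NF-kB genes (5 of 20, and 7 adjusted over the list alone, 3.2e-10) and interferon response genes (5 of 23, and 6 adjusted over the list alone, 0.00047). With an estimated correlation their adjusted p-values were 0.00045, 0.00012 and 0.018. Nfkbie rose by 1.40 ± 0.20, Relb, an NF-kB subunit gene, by 0.92 ± 0.16, Irf1 by 1.44 ± 0.31 and Gbp3 by 1.38 ± 0.25. Of 17 acute phase and innate defence genes 4 rose, among them Tlr2 by 1.56 ± 0.16, and 5 when adjusted over the list alone (camera adjusted p = 0.00058, and 0.051 with an estimated correlation). Of 36 immediate early genes 5 rose, with Atf3 by 1.63 ± 0.30 and Ier3 by 1.58 ± 0.18, and 11 rose and 1 fell when adjusted over the list alone (camera adjusted p = 4.3e-07, and 0.051 with an estimated correlation). Of 17 adhesion genes 3 rose, with Icam1 by 1.67 ± 0.30 and Adamts1 by 0.84 ± 0.16, and 4 when adjusted over the list alone (camera adjusted p = 0.043, and 0.2 with an estimated correlation).

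A further 3 lists, of cell types and synapses, passed only at the preset correlation in AcP+AcPb neurons. Synaptic receptors and channels were lower without a called member (camera adjusted p = 0.03, and 0.54 with an estimated correlation). Oligodendrocyte markers were higher without a called member (camera adjusted p = 0.043, and 0.52 with an estimated correlation). Progenitor and dividing cell markers were higher, with a rise of the replication gene Mcm5 by 0.67 ± 0.13 (camera adjusted p = 0.023, and 0.46 with an estimated correlation).

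**Figure D2:**
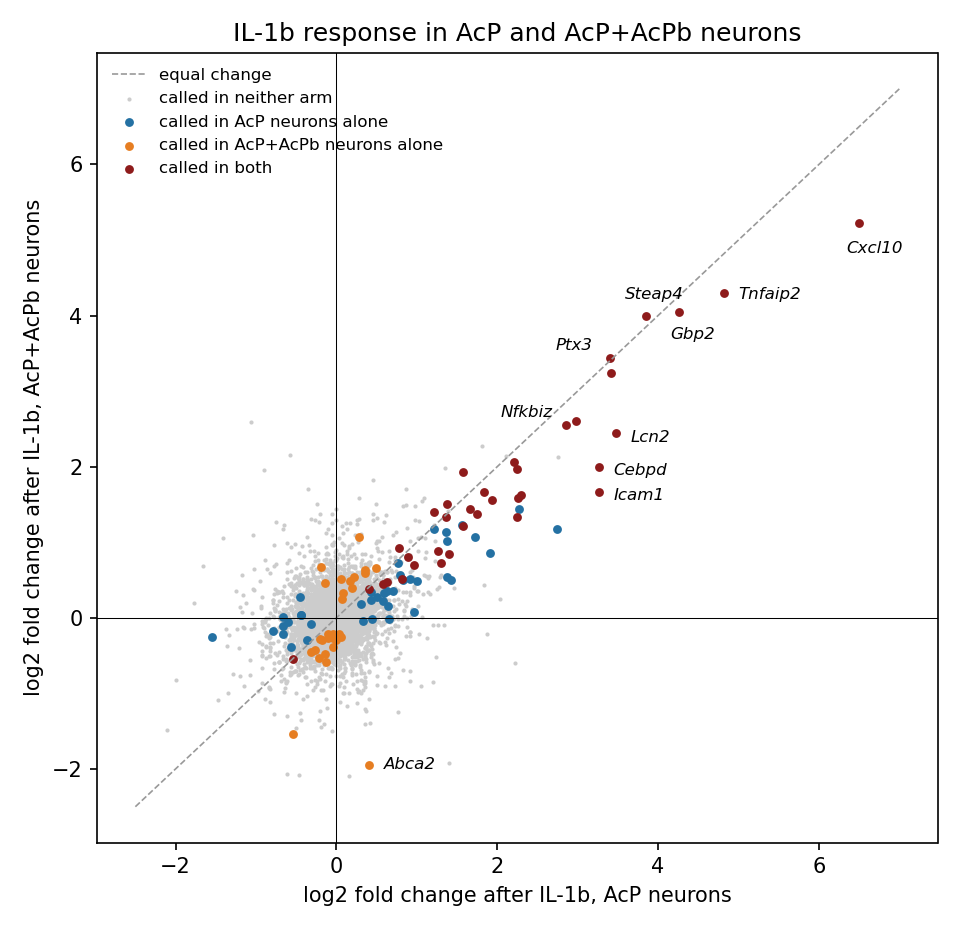
Log2 fold change after IL-1b of each of 14221 genes in AcP neurons (horizontal axis) and AcP+AcPb neurons (vertical axis), on the log2(intensity + 16) scale, coloured by the arm in which limma called the gene, with a dashed line at equal change. Of the 47 genes that rose in AcP+AcPb neurons, 35 also rose in AcP neurons.

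The genes raised in AcP and in AcP+AcPb neurons overlapped, with 35 shared among the 63 and 47, where independent lists would share 0.21 (Fisher's exact test p = 1.5e-77). Cxcl10, Ccl2, Gbp2, Nfkbiz, Lcn2 and Cebpd were among them. Nrarp was the 1 shared fall among 13 and 18, where 0.02 would be shared (Fisher's exact test p = 0.016). No array enters both responses, but limma estimated each gene's variance over all arrays, for both responses alike. Genes with a small variance are thus called more readily in both, which raises the overlap expected of unrelated responses. Fisher's exact test does not allow for this or for genes that vary together, so its p-values may be too small. Across the 14221 genes the changes correlated at Pearson's r = 0.399 and Spearman's rho = 0.247, and across the 105 genes called in either arm at 0.917 and 0.888, although genes are not independent replicates. Of these 105 genes, 92 had the same sign in both arms and 69 had the smaller change in AcP+AcPb neurons. They were picked by their calls in these same responses, 76 in AcP and 65 in AcP+AcPb neurons. Picking them so raises the correlation and the share of equal signs. The larger number of calls in AcP neurons favours a smaller change in AcP+AcPb neurons.

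**Figure D3:**
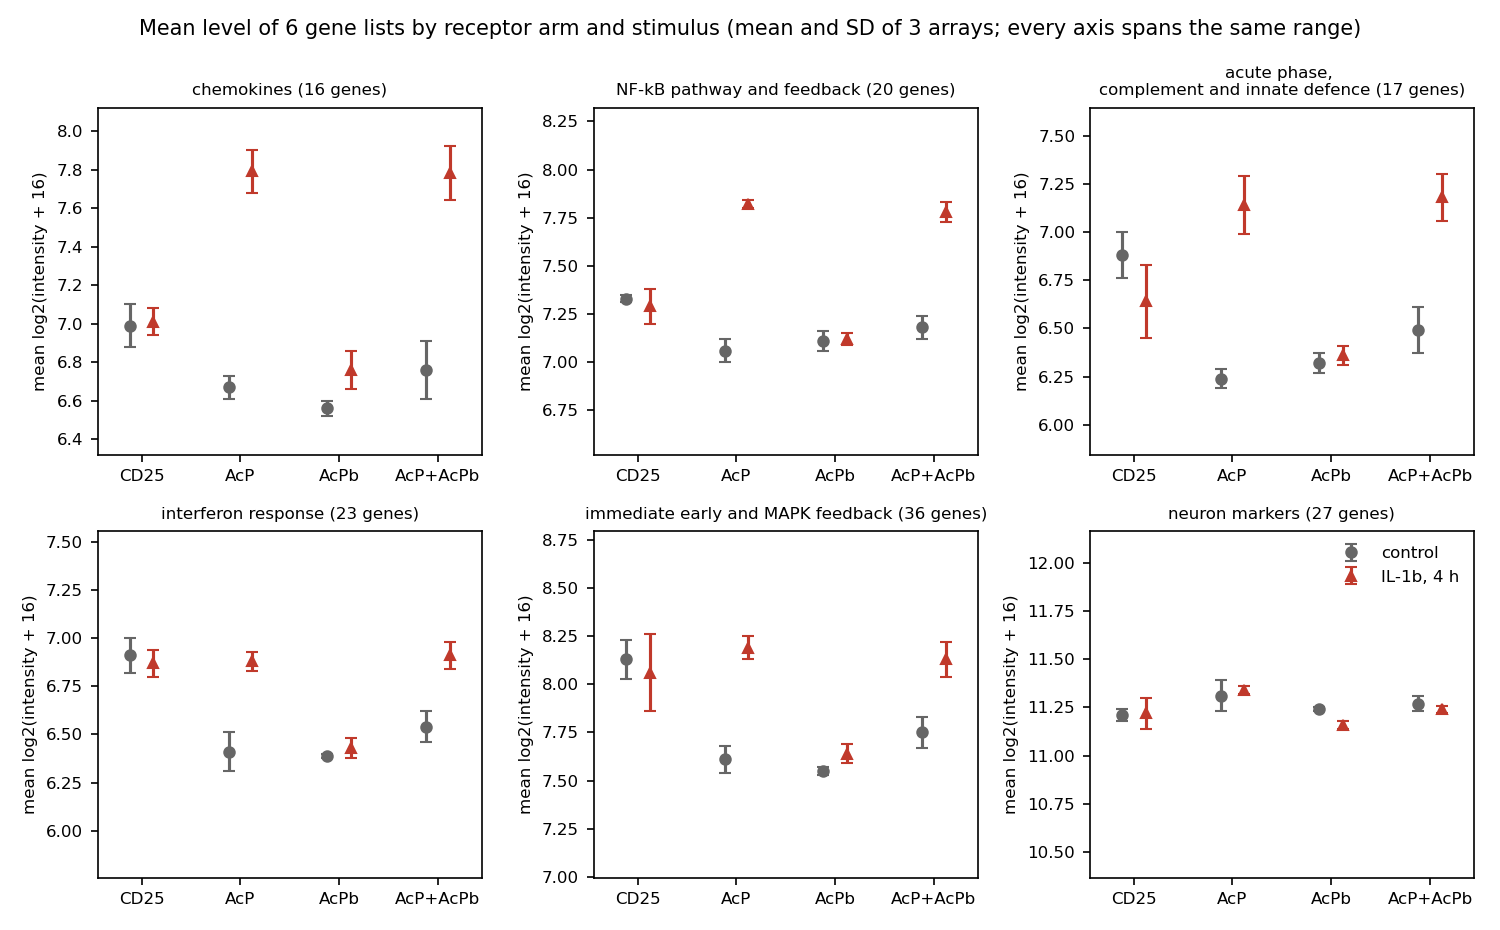
Mean log2(intensity + 16) over the tested members of 6 gene lists, by receptor arm, for control arrays (grey circles) and IL-1b arrays (red triangles), with the SD of 3 arrays as bars and the same span on every vertical axis. Chemokines averaged 7.79 after IL-1b in AcP neurons, 7.78 in AcP+AcPb neurons and 6.76 in AcPb neurons.

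The response with AcP differed from that with CD25 in chemokine, NF-kB and defence genes. The difference in log2 change was 6.54 ± 0.45 for Cxcl10 (adjusted p = 1.4e-07), 5.23 ± 0.33 for Tnfaip2, 4.75 ± 0.43 for Steap4, 4.34 ± 0.39 for Gbp2, 3.97 ± 0.45 for Lcn2 and 3.82 ± 0.38 for Ptx3. It was 3.53 ± 0.43 for Icam1, 3.42 ± 0.37 for Cebpd, 3.34 ± 0.29 for Ccl2, 3.29 ± 0.25 for Nfkbiz, 2.98 ± 0.34 for Cxcl2 and 2.55 ± 0.28 for Egr2. Lower responses with AcP were called for Abhd2 at -0.77 ± 0.13, Fyco1 at -0.77 ± 0.11 and Gm15850 at -2.52 ± 0.49, which had means below 0 in both AcP groups and went from -13.1 to 46.6 in CD25 neurons, a change that was not called by itself. The other Abhd2 probe set was uncalled and opposite in sign at 0.47 (adjusted p = 0.87). CD25 controls already held Cebpd at 823 ± 53.4 against 68.2 ± 14.4 in AcP controls, a higher starting level from which its response in CD25 neurons was measured. limma called 35 genes, 32 higher and 3 lower, and 226 without AcP control 3 or 58 over single probe sets. Chemokines (6 of 16 members), acute phase and innate defence genes (4 of 17), NF-kB genes (3 of 20), interferon response genes (4 of 23), immediate early genes (7 of 36) and adhesion genes (3 of 17) were higher in the AcP response at both correlations. Adjusted over the list alone these counts were 6, 7, 7, 6, 9 and 6, with 2 lower adhesion genes. Apoptosis genes were called at the preset correlation (camera adjusted p = 0.016, and 0.11 with an estimated correlation). Of the 15 named genes, 11 were called under every alternative, and Gm15850 lost its call in 12 of 25.

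The arrays do not check that the AcPb cultures made AcPb, so whether AcPb can take the place of AcP is not settled here. For most of these genes the response with AcPb minus that with AcP was called negative. The difference was -6.14 ± 0.45 for Cxcl10 (adjusted p = 4.1e-07), -4.86 ± 0.33 for Tnfaip2, -3.91 ± 0.39 for Gbp2, -3.85 ± 0.43 for Steap4, -3.51 ± 0.29 for Ccl2, -3.26 ± 0.37 for Cebpd, -3.12 ± 0.45 for Lcn2 and -3.07 ± 0.43 for Icam1. Chemokines (5 of 16 lower), NF-kB genes (3 of 20), acute phase and innate defence genes (4 of 17), interferon response genes (3 of 23) and immediate early genes (6 of 36) were lower at both correlations, and adjusted over the list alone the counts were 6, 7, 6, 6 and 9, with 1 acute phase and 1 interferon gene higher. Of 17 adhesion genes 2 were lower, and adjusted over the list alone 5 lower and 1 higher, but the list was not called (camera adjusted p = 0.12). Positive differences were called for Six3os1 at 1.07 ± 0.21, Eci3 at 1.01 ± 0.20, Gm4802 at 0.49 ± 0.10 and Wtip at 0.35 ± 0.07, none of which kept its call with array medians centred or under quantile normalization. limma called 37 genes, 4 higher and 33 lower, against 0 and 31 under quantile normalization and 0 and 38 with array medians centred, which took the median over all genes from -0.007 to -0.107. Neuron markers were lower, and oligodendrocyte, progenitor and endothelial, mural and fibroblast lists higher, at the preset correlation (adjusted p with an estimated correlation 0.37, 0.37, 0.2 and 0.14).

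Between AcPb and CD25 neurons the responses differed for 3 genes by limma. Gm15850 differed by -3.85 ± 0.49 (adjusted p = 0.0047), made up of -1.90 in AcPb neurons, from 46.1 to -22.1, and 1.95 in CD25 neurons, from -13.1 to 46.6, neither of which was called by itself, Peak1 by -1.24 ± 0.20 (adjusted p = 0.049) and Ppip5k2, an inositol pyrophosphate kinase gene, by 0.78 ± 0.13 (adjusted p = 0.049). None of the 20 lists was called at either correlation or with fry. Peak1 lost its call in 18 of 26 alternatives, Ppip5k2 in 17 of 26 and Gm15850 with the generalised log. The count was 7 without CD25 IL-1b array 1, 11 without AcPb IL-1b array 1, 1 without CD25 IL-1b array 2, AcPb control 1 or 3, or AcPb IL-1b array 2 or 3, and 24 with array weights.

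Adding AcPb to AcP left 1 called difference in response, Lsm7, while several inflammatory genes rose less, from higher control means, with no difference called. This component of RNA processing complexes differed by 0.79 ± 0.09 (adjusted p = 0.0013), from 325 ± 23.9 in AcP+AcPb controls to 699 ± 47.1 after IL-1b, against 634 ± 53.5 and 771 ± 5.38 for Lsm7 in AcP neurons. Its difference in response thus goes with a low level in the AcP+AcPb controls, not with a higher stimulated level. The difference was -1.60 for Icam1 (adjusted p = 0.65), -1.28 for Cxcl10 (adjusted p = 0.82), -1.26 for Cebpd (adjusted p = 0.69), -1.04 for Lcn2 (adjusted p = 0.93) and -0.52 for Tnfaip2. Means of AcP+AcPb and AcP controls were 54.3 and 13.5 for Cxcl10, 79.1 and 12.5 for Icam1 and 18.1 and 8.85 for Tnfaip2. For Cebpd they were 157 and 68.2, and for Lcn2 81.8 and 44.8. After IL-1b they were 2489 and 2512 for Cxcl10, 677 and 693 for Tnfaip2, 653 and 809 for Cebpd and 524 and 622 for Lcn2. Icam1 ran from 191 to 376.8 on AcP+AcPb arrays, against a mean of 274 in AcP neurons. AcP control means of Cxcl10, Icam1 and Tnfaip2 lay below the added 16. Over the lists, NF-kB genes (camera adjusted p = 0.032), acute phase and innate defence genes (0.022) and immediate early genes (0.0012) responded less with both chains at the preset correlation. Oligodendrocyte (0.00036) and progenitor markers (1.3e-05) responded more. With an estimated correlation the adjusted p-values were 0.2, 0.24, 0.28, 0.24 and 0.2, and fry called 0 lists. No list member was called over all genes, and adjusted over the list alone 1 oligodendrocyte marker, 2 progenitor markers and 1 cytokine or growth factor gene were higher and 1 adhesion gene was lower. At an unadjusted p under 0.05 there were 751 genes against 711 from chance. The count was 4 without AcP control 3, 3 without AcP+AcPb control 3, 2 without AcP IL-1b array 3 and 0 with array medians centred or with only these 12 arrays, which end the call of Lsm7.

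Without IL-1b, several genes that IL-1b raised in AcP neurons, among them Cebpd, Icam1 and Gbp2, were already higher in CD25 than in AcP neurons. The receptor gene Tnfrsf12a was lower in AcP controls by a log2 difference of -4.31 ± 0.62 (-134 against 307). Tagln, an actin-binding protein of contractile cells, differed by -4.02 ± 0.54 (70.3 ± 55.4 against 1140 ± 305), Cd109 by -3.97 ± 0.39 (5.52 against 340) and Glycam1 by -3.56 ± 0.68 (3.97 against 328). S1pr3, a receptor for sphingosine 1-phosphate, differed by -3.52 ± 0.20 (263 ± 27.5 against 3195 ± 350, adjusted p = 7e-09) and Cebpd by -3.33 ± 0.26 (68.2 against 823). Higher in AcP controls were the dim genes Cort at 2.14 ± 0.69, 1110017D15Rik, Il1f8, Omp, Gm10037 and Abca12, with CD25 means between -19.6 and 17.4. Cort lost its call in 11 of 20 alternatives, Omp in 11 of 18, Il1f8 in 7 of 20, Gm10037 in 4 of 19, 1110017D15Rik in 3 of 19 and Abca12 in 1 of 19, and 5 of the 12 named genes kept theirs in all. Il1r2 was lower in AcP controls by -1.25 ± 0.39 (adjusted p = 0.036), 11.6 against 52.0.

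Of the 20 lists, 9 were called between AcP and CD25 controls at both correlations, with estimated-correlation adjusted p-values of 0.025 to 0.044. Lower in AcP were 8 of 17 adhesion genes (Timp1 -3.18, Icam1 -2.90, Cd44 -2.03), 11 of 23 interferon response genes (Gbp2 -2.22), 13 of 36 immediate early genes (Socs3 -3.10, Fos -1.44), with 2 higher, and 6 of 17 acute phase genes (Serpina3n -2.26, Ptx3 -1.85). Also lower were 7 of 20 NF-kB genes, with 1 higher, 10 of 18 progenitor and dividing cell markers (Birc5 -1.69, Ccnb2 -1.30, Cdk1 -1.26), with 1 higher, the Notch target Hes5 at 1.20, and 7 of 15 endothelial, mural and fibroblast markers (Tagln, Fn1 -1.76, Acta2 -1.42). The last were 8 of 16 apoptosis genes (Fas -2.10) and 7 of 21 stress genes (Nqo1 -1.74, Hspb1 -1.60), with 1 higher. Adjusted over the list alone the lower counts were 8, 11, 15, 6, 7, 13, 9, 10 and 7. Of 27 neuron markers 6 were higher in AcP, with Nefh at 0.38 and Syn1 at 0.28, and of 33 synaptic genes 5, with the potassium channel gene Kcnq3 at 0.65 (camera adjusted p = 0.0038 and 0.00041, and adjusted p = 0.29 and 0.24 with an estimated correlation). Of 16 chemokines 3 were lower in AcP and the list passed fry (adjusted p = 0.0013) but not camera (adjusted p = 0.13), and cytokines, 2 higher and 1 lower of 19, passed neither (adjusted p = 0.24 and 0.63). Astrocyte markers went both ways, with 6 higher and 4 lower of 16, and Gfap at -1.98. limma called 2211 genes, 975 higher and 1236 lower in AcP, 264 of them at least 2-fold, with 28.1% of genes without overlap, where chance gives 10%. The count was 1383 with array weights and 547 with only these 6 arrays.

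AcPb controls differed from CD25 controls in many of these genes too. Tnfrsf12a was lower in AcPb by -3.96 ± 0.62 (-49.5 against 307), Glycam1 by -3.37 ± 0.68 (15.7 against 328) and Trim47 by -3.24 ± 0.51 (-46.9 against 137). Cd109 was lower by -3.23 ± 0.39 (21.2 against 340), Cebpd by -3.17 ± 0.26 (76.9 against 823, adjusted p = 8.7e-07) and Tagln by -3.13 ± 0.54. Higher in AcPb, from CD25 means of at most 45.7, were H2-DMb2 at 2.85 ± 0.80, whose other probe sets were uncalled and opposite in sign, Gm15850 at 1.90 ± 0.35, Hoxc5, Gm11627, Wdcp and Lad1. Of these only Gm15850 kept its call under every alternative, while Lad1 lost it in 13 of 20, Hoxc5 in 12 of 18, H2-DMb2 in 11 of 20, Wdcp in 7 of 19 and Gm11627 in 6 of 19. Interferon response genes were lower in AcPb, 8 of 23 members and 12 adjusted over the list alone, with Gbp2 at -1.91 and Gbp3 at -1.56 (camera adjusted p = 4.7e-06, and 0.0062 with an estimated correlation). So were immediate early genes, 14 of 36 with 1 higher, and 18 adjusted over the list alone, with Socs3 at -2.90 and Fos at -1.50 (camera adjusted p = 4.1e-09, and 0.045 with an estimated correlation). Chemokines, NF-kB, acute phase, adhesion, endothelial, mural and fibroblast, apoptosis, stress and progenitor lists were lower at the preset correlation and with fry, with adjusted p-values of 0.054 to 0.19 with an estimated correlation. Cxcl10 was at -2.93 and Gfap at -1.73. limma called 1083 genes, 336 higher and 747 lower in AcPb, 167 of them at least 2-fold, with 32.7% of genes without overlap, where chance gives 10%. The count was 2076 with array weights, 701 with array medians centred, 685 without CD25 control 2, 669 without CD25 control 3, 667 without AcPb control 1 and 681 without AcPb control 3.

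AcP+AcPb controls differed from AcP controls in few genes, among them the astrocyte filament gene Gfap, higher by 1.49 ± 0.29 (1360 ± 378 against 482 ± 178, adjusted p = 0.033). Icam1 was higher by 1.64 ± 0.30 (79.1 against 12.5), A2m, a protease inhibitor gene, by 1.13 ± 0.16 and Foxo4 by 1.13 ± 0.21 (27.9 against 3.13). Osmr, the oncostatin M receptor, was higher by 0.98 ± 0.17 and Dcxr by 0.83 ± 0.16. Lower were Mapk15 at -2.05 ± 0.32 (-35.8 against 52.1), Prorp at -1.14 ± 0.23 and Lsm7 at -0.93 ± 0.07 (325 against 634, adjusted p = 4.5e-07). Coq6 was lower at -0.87 ± 0.11, the myelin lipid enzyme gene Ugt8a at -0.85 ± 0.15 and Pclaf at -0.82 ± 0.12. NF-kB, acute phase, adhesion, interferon and immediate early lists were higher, and oligodendrocyte and progenitor markers lower, at the preset but not the estimated correlation. With an estimated correlation their adjusted p-values were 0.1, 0.091, 0.1, 0.091, 0.32, 0.21 and 0.1, and fry called the interferon (0.043), oligodendrocyte (0.043) and progenitor (0.014) lists. limma called 35 genes, 13 higher and 22 lower, and the array codes of these 2 groups do not overlap, so code and arm cannot be told apart here. None of the 12 named genes kept its call under every alternative, Gfap lost it in 8 of 19 with its other probe sets uncalled (adjusted p = 0.071), and 4 of 10 splits of these arrays, the real one included, called at least 35 genes. The count was 20 without AcP control 1, 64 without AcP control 2, 162 without AcP control 3, 87 without AcP+AcPb control 1, 13 without AcP+AcPb control 2, 21 with array medians centred, 17 with the mean of probe sets, 55 over single probe sets, 2 with array weights and 1 with only these 6 arrays.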

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

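The splits of the stimulus labels within each arm, and the tests of a raised unstimulated level, were chosen after the results were seen, whereas the splits of whole arrays and the array code test were written before the data were examined.

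The IL-1b responses of AcP and CD25 neurons differed in 35 genes. The differences were 6.54 for Cxcl10, 5.23 for Tnfaip2, 4.75 for Steap4, 4.34 for Gbp2, 3.97 for Lcn2, 3.82 for Ptx3, 3.53 for Icam1, 3.42 for Cebpd, 3.34 for Ccl2, 3.29 for Nfkbiz, 2.98 for Cxcl2 and 2.55 for Egr2, and -2.52 for Gm15850, -0.77 for Abhd2 and -0.77 for Fyco1. Of 100 splits that moved arrays between the arms, 12 called at least as many genes, and the highest other split called 3409. By the reading written before, these splits do not tell the count apart from a random assignment of arrays to arms. Such splits mix arms that already differ without IL-1b, and whether this gives their many calls was not tested. Of 100 splits that moved the stimulus labels within each arm, 4 reached 35, and the highest other called 49.

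The responses of AcPb and AcP neurons differed in 37 genes, by -6.14 for Cxcl10, -4.86 for Tnfaip2, -3.91 for Gbp2, -3.85 for Steap4, -3.51 for Ccl2, -3.26 for Cebpd, -3.12 for Lcn2 and -3.07 for Icam1, and by 1.07 for Six3os1, 1.01 for Eci3, 0.49 for Gm4802 and 0.35 for Wtip. Of 100 splits between the arms 6 reached this count, with 1646 as the highest other, so these splits do not tell the count apart from a random assignment of arrays to arms. Unstimulated AcPb and AcP neurons were not compared, so whether an arm difference without IL-1b gives these calls was not tested. With stimulus labels moved within each arm 3 of 100 reached it, with 58 as the highest other.

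The responses of AcPb and CD25 neurons differed in 3 genes, by 0.78 for Ppip5k2, -3.85 for Gm15850 and -1.24 for Peak1. Of 100 splits between the arms 13 reached 3, with 1422 as the highest other, so these splits do not tell the count apart from a random assignment of arrays to arms. With stimulus labels moved within each arm 1 of 100 reached 3, with 2 as the highest other. The responses of AcP+AcPb and AcP neurons differed in 1 gene, Lsm7, by 0.79. Of 100 splits between the arms 39 reached 1, with 380 as the highest other, and 34 of 100 did so within each arm, with 25 as the highest other, so this count is not told apart from a random assignment of the arrays.

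For the responses themselves there are only 10 splits of 3 against 3 arrays, too few for a share under 0.05. The AcP response of 76 genes was reached by 1 split, the real one, with 4 as the highest other, the AcP+AcPb response of 65 by 1, with 2 as the highest other, and the AcPb response of 1 by 1, with 0 as the highest other. The CD25 response of 0 was reached by all 10, and the highest other split called 42.

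The lack of a response in CD25 neurons might come from genes that were already raised there and had no room to rise. Of the 63 genes that rose in AcP neurons, 16 had a CD25 control level at most 0.25 log2 units above that of AcPb controls, called or not. Their median change was 0.98 in AcP and 0.03 in CD25 neurons, which argues against this explanation for them as a set. The bootstrap standard error of 0.04, like those of the other genes below, was taken over genes. It does not measure the spread between arrays or cultures. The explanation stays open for Rfx2, Hmgxb3, Rasl11b and Bcor among these genes. limma did not call these lower in CD25 controls than in stimulated AcP neurons (adjusted p = 0.94, 0.44, 0.19 and 0.054). Of the other 47, limma called 16 in CD25 controls below their level in stimulated AcP neurons, by a median of 1.68, in a test chosen after the values were seen. Their median change in CD25 neurons was -0.16, with a standard error of 0.08, so a lack of room does not explain these 16 either. For the remaining 31, among them Cebpd and Icam1, the median distance was -0.07, with a standard error of 0.10, and the explanation remains open.

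NF-kB, acute phase and immediate early genes responded less in AcP+AcPb than in AcP neurons at the preset correlation, by -0.19 log2 units over 73 members, with a standard error of 0.08. None of the 3 lists kept its call with an estimated correlation (adjusted p = 0.2, 0.24 and 0.28) or with fry, so whether the responses differ at all is open. If they do, this could come from a higher unstimulated level. The unstimulated difference was 0.16 and the stimulated difference -0.03, with a standard error of 0.06, as a higher starting level with an equal end level gives. It could also come from the array code, and with the code as a block the difference was -0.28, with a standard error of 0.10. That value did not shrink, which by the reading written before would speak against the code, but this reading was set aside because only 1 AcP+AcPb control array shares the code of the IL-1b arrays, and the question stays undecided.

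Probe sets without a single gene name numbered 4836 past the filter, of which IL-1b changed 2 in AcP neurons, 1 of them higher, and 3 in AcP+AcPb neurons, all higher.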

How the results depend on the processing

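The generalised log was chosen after the data were seen, and all other alternatives were fixed before. Groups of 3 arrays and signals partly below 0 limit what could be seen, above all small changes of dim genes. For the values that moved the cause was not tested. Numbers are genes called, unless lists are named.

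Array weights gave 2 genes in CD25 (0 before), 34 in AcP (76), 179 in AcPb (1), 24 in AcPb minus CD25 (3), and 1383, 2076 and 2 in unstimulated AcP minus CD25 (2211), AcPb minus CD25 (1083) and AcP+AcPb minus AcP (35). Only the arrays compared gave 31 in AcP, 0 in AcPb, 9 in AcP+AcPb (65), 0 in AcP+AcPb minus AcP (1), and 547 and 1 in unstimulated AcP minus CD25 and AcP+AcPb minus AcP. Array medians centred gave 42 in AcP+AcPb, 1 in AcPb minus CD25, 0 in AcP+AcPb minus AcP, and 701 and 21 in unstimulated AcPb minus CD25 and AcP+AcPb minus AcP. All probe sets tested singly gave 123 in AcP, 3 in AcPb, 58 in AcP minus CD25 (35), 1 in AcPb minus CD25 and 55 in unstimulated AcP+AcPb minus AcP. The mean of probe sets gave 0 in AcPb, 1 in AcPb minus CD25 and 17 in unstimulated AcP+AcPb minus AcP. No dim filter gave 2 in AcPb, 6 in AcPb minus CD25 and 3 in AcP+AcPb minus AcP, and a filter at the 60th percentile 2 in AcPb. An intensity trend gave 2 in AcPb and 2 in AcP+AcPb minus AcP. The array code block gave 23 in AcP+AcPb, 1 in AcPb minus CD25 and 2 in AcP+AcPb minus AcP, and could not be fitted to unstimulated AcP+AcPb minus AcP. In AcPb minus CD25, pseudocount 1 gave 1 and the generalised log 0.

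Same-numbered control and IL-1b arrays deviated together at r = -0.133 to 0.237 over 12 pairs, and for 4 of 12 the best partner was the own number. These 4 lay in the CD25 and AcPb arms, where r ran from 0.025 to 0.237. With the replicate block the AcPb minus CD25 count was 1 and 1 list was called in AcPb (0). Only the number of lists was recorded, so which list it was and its direction are not given. The block joins the same number over all arms, so pairs within an arm were not modelled. Lists called with an estimated correlation were 3 in AcP+AcPb (9), 0 in AcP+AcPb minus AcP (5), 5 in AcPb minus AcP (9), and 2 and 0 in unstimulated AcPb minus CD25 (10) and AcP+AcPb minus AcP (7). With fry they were 0 in AcP+AcPb minus AcP, 5 in AcPb minus AcP and 3 in unstimulated AcP+AcPb minus AcP. The correlation of AcP and AcP+AcPb responses (0.399) was 0.917 over called genes, which were picked by these responses, and 0.335 without the dim filter.

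Leaving out each array in turn gave 0 to 1 in CD25, 38 to 189 in AcP, 1 to 4 in AcPb, 29 to 120 in AcP+AcPb, 29 to 226 in AcP minus CD25, 1 to 11 in AcPb minus CD25, 1 to 4 in AcP+AcPb minus AcP, 25 to 44 in AcPb minus AcP, and 1498 to 3243, 667 to 768 and 13 to 162 in unstimulated AcP minus CD25, AcPb minus CD25 and AcP+AcPb minus AcP. The correlation ran from 0.312 to 0.437.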

Other observations

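The gene families, the share among other genes higher in CD25 neurons, the list contrast used for the share of neurons and the comparison of array medians were chosen after the values were seen, and the tests of RNA integrity, of fibroblasts, of Notch genes and of stimulated CD25 arrays were written before.

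Of the guanylate-binding protein genes, interferon-inducible GTPases, the 4 past the dim filter rose in both responding arms, Gbp2 by 4.26 and 4.05, Gbp3 by 1.75 and 1.38, Gbp6 by 1.36 and 1.34 and Gbp7 by 1.58 and 1.22 in AcP and AcP+AcPb neurons, and 0 were called in AcPb or CD25 neurons. The filter passes a gene that is bright in only 3 arrays, so a member that is dim without IL-1b enters more readily if it rises, and no test of the family was made. Of 8 class I antigen presentation genes, 2 rose in AcP neurons, H2-K1 by 0.81 (adjusted p = 3.4e-05) and the peptide transporter Tap2 by 1.36 (adjusted p = 0.015), and 1 in AcP+AcPb neurons, H2-K1 by 0.52. Of 13 replication licensing genes, 0 were called in AcP neurons and 3 rose in AcP+AcPb neurons, Mcm5 by 0.67 (adjusted p = 0.028), Mcm4 by 0.51 (adjusted p = 0.045) and Dbf4 by 0.49 (adjusted p = 0.037). Their differences between the arms, 0.86 for Mcm5, 0.45 for Mcm4 and 0.31 for Dbf4, were not called (adjusted p = 0.38, 0.82 and 0.94), Mcm5 was already lower in AcP+AcPb than AcP controls by 0.75 (adjusted p = 0.022), and with the array code as a block only 16 of the 65 genes called in AcP+AcPb neurons were called again.

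Unstimulated CD25 neurons differed from AcP neurons in 2211 genes and from AcPb neurons in 1083. Each count was reached by 1 of 10 splits, the real one, with 0 as the highest other, and the 35 genes between AcP+AcPb and AcP controls by 4 of 10, with 104 as the highest other. RNA integrity is an unlikely cause, since the 3' minus 5' signal of Actb and Gapdh differed by 0.01, with an SD of 0.05. A lower share of neurons that raises all other cell types alike has only weak evidence against it. Between CD25 and AcPb controls the endothelial, mural and fibroblast list exceeded the microglia list, of 8 genes, by 0.86, with a standard error of 0.18. The microglia list was dim, with means of 6.24 and 6.55 log2 units in CD25 and AcPb controls, so a rise in it could be missed. Other shifts in cell types are not excluded by this gap. CD25 minus AcPb controls was 0.54 for endothelial, mural and fibroblast, 0.31 for progenitor, 0.06 for astrocyte, -0.03 for neuron, -0.19 for oligodendrocyte and -0.31 for microglia markers. Fibroblasts in the cultures would raise collagens with Tagln, but the median over collagen genes, Dcn and Lum was 0.34, against a bound of 0.5 set before. Its standard error of 0.10 is over these genes, not over arrays. The collagens were higher in CD25 than AcPb controls without a call, Col1a1 by 0.54, Col1a2 by 0.45, Col6a1 by 0.41 and Col3a1 by 0.28. Dcn was at 0 and Lum at -0.01. A small share of fibroblasts is thus not excluded. A culture batch of the CD25 arm was not tested and stays open.

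Genes that IL-1b raised in AcP+AcPb neurons were often the ones already higher in unstimulated CD25 than AcPb neurons, 26 of 47 where 2.47 would be shared (Fisher's exact test p = 1.5e-21), with no array in common. For AcP neurons it was 35 of 63, where 3.31 would be shared (Fisher's exact test p = 1.2e-28). The calls compared here still share each gene's variance over all arrays, and genes can vary together. Both p-values may therefore be too small. Of the 26, 14 (53.8%) were again higher in stimulated CD25 than stimulated AcPb neurons, on other arrays. Of the other 721 genes higher in unstimulated CD25 neurons 256 (35.5%) were again higher (Fisher's exact test p = 0.063), so the IL-1b genes were not told apart from the others in this. The cause was not tested.

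Nrarp fell in both responding arms on the probe set used, while its other probe set was uncalled (adjusted p = 0.23 and 0.22) and the call was lost in 2 of 20 alternatives in each arm. A Notch list of 20 genes without Nrarp and Notch2 had 12 lower in AcP neurons, with a mean of -0.10 and p = 0.05 by camera (0.23 with an estimated correlation), and 10 lower in AcP+AcPb neurons, with p = 0.86, and 0 genes were called. Whether Notch signalling changed remains undecided at that larger p of 0.86.

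Medians of control and IL-1b arrays with the same replicate number differed by only 0.01 to 0.03 intensity units in the CD25 arm, against 0.55 to 11.39 in the AcP, 0.99 to 4.31 in the AcPb and 0.47 to 3.13 in the AcP+AcPb arm. No array pair held identical values, and the cause was not tested.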
